A study of Mus musculus with 12 samples.

How the data were processed

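Lymph node RNA of 12 mice libraries was measured by RNA-seq, 3 libraries for each of 4 groups. Per the labels' protocols, total RNA was extracted with Trizol and mRNA libraries were made by a standard Illumina procedure. The deposited values are whole-number read counts per gene in 1 table of 55487 genes, not normalized by the authors. Per the submitters' processing notes, HISAT2 2.0 was used with the mm10 genome build. The read counter, the gene annotation, the strand setting and any filter on reads mapping to several places are not given in the sources used here. Reads shared by near-identical genes, overlapping genes or antisense partners may therefore be divided in a way that cannot be checked. The labels call the 3 libraries of a group biologically independent repetitions, and they do not say whether 1 library holds 1 mouse or several. Library totals ran from 16862953 to 24467873 counts, and IDs without a symbol took at most 0.0548% of them.

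The groups, the tests, the 51 gene lists, the rule for naming genes and most alternative fits were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization (factors from 0.967 to 1.01), filterByExpr by group with a minimum count of 10 and a minimum total of 15 (17301 genes kept), and the robust quasi-likelihood fit of 1 mean per group over all 12 libraries. The contrasts were T NC against NT NC, T NDE against T NC, NT NDE against NT NC, T NDE against NT NDE and the interaction, (T NDE - T NC) - (NT NDE - NT NC). P values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and all tests are two-sided. Group values are normalized counts scaled to library size (CPM, edgeR cpm) as mean ± SD. The CPM of Bpifa2 and Hbb-bs by library and of the summed pigment genes were scaled to library totals without TMM factors. An exact permutation of 3 libraries against 3 cannot give p under 0.1, so gene-level tests rely on the spread shared across genes. Changes for T NC against NT NC were simulated at this depth with the fitted dispersion of each gene (17301 genes, 250 changed genes per fold size over 5 draws). They were recovered in 48.8% of genes at 1.5-fold, 65.6% at 2-fold, 80.8% at 3-fold and 89.2% at 4-fold, with a mean of 10 unchanged genes called per draw. Genes were drawn independently and without an excess in single libraries. These shares therefore need not hold for the real libraries, and a lack of calls does not show that such changes are absent.

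Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01 as the main test, and camera with an estimated correlation and fry beside it, adjusted over the 51 lists of a contrast. With an estimated correlation 0 lists passed in any contrast (smallest adjusted p 0.0650, 0.222, 0.102, 0.513 and 0.0990 in the order above, with 5, 8, 5, 4 and 5 lists at an unadjusted p under 0.05). For each list, members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. In each contrast the 8 lists with the smallest camera p, leaving out the salivary gland list, are described, and further lists were added after their values were seen. The salivary gland list itself had medians of -6.79, 7.49, -8.25, 8.98 and 16.09 in the 5 contrasts, with camera adjusted p of 1.47e-06, 4.01e-05, 7.88e-07, 4.82e-07 and 1.09e-11, and each call was lost with an estimated correlation (adjusted p = 0.552, 0.477, 0.542, 0.678 and 0.303 with an estimated correlation). Of the 14 tested members, 12 passed for the interaction when adjusted over the list alone.

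Genes were named by a fixed rule. For each contrast these were the 10 highest and 10 lowest fold changes among genes passing the threshold with at least 1 CPM and no overlap between the groups, leaving out antigen receptor segments and unnamed or predicted genes, then up to 3 passing members of each called list until 30 genes were named. Where fewer than 5 genes passed, all passing genes and the 10 with the smallest p were named as values only. Melanocyte genes that passed the count filter and the receptor genes Calcrl, Ramp1 and Tacr1 were tested in every contrast. Other melanocyte genes held too few counts to be tested. The rule named a further gene that is not reported here. Because fewer than 5 genes passed in each contrast, the list examples given are the 3 members with the smallest p of a called list, a choice made after that was known. Genes named from DESeq2 calls, from fits with fewer libraries or from the closing tests were also chosen after their values were seen. Positions are from GENCODE release M21 on mm10, and Gm4617 was compared with GENCODE transcripts by BLAST 2.17.0.

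Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors and upper-quartile factors in the edgeR fit, limma-voom, no filter, a stricter filter (1 CPM in at least 3 libraries), antigen receptor genes left out, a replicate block, the 6 libraries of a comparison alone, and each library left out in turn. Leaving out 1 library lowers the smallest group to 2, so that filterByExpr then keeps more low genes. After the salivary signal was seen, fits without the 3 or the 2 most salivary libraries and with log2 CPM of Bpifa2 as a covariate were added. Without the 3 libraries, NT NC holds 1 library, whose spread is taken to be that of the other groups. No pair of libraries within a group was identical (chi-square per degree of freedom from 6.30 to 76.0), so all 12 were counted. Figures were drawn with matplotlib 3.10.9.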

Results

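Bulk RNA-seq gene counts were analysed for lymph nodes of mice in a factorial design with 4 groups. One factor was a tumour: T mice had received B16F10 melanoma cells in the tongue and NT mice had not. The other was the pain-sensing (nociceptive) innervation of the tumour-draining lymph node, which had been inhibited in NDE mice and left intact in NC mice. The series concerns draining nodes before metastasis, so the comparisons ask what a tumour does to the node transcriptome, what silencing the nerves does, and whether either effect depends on the other. Each group (NT NC, T NC, NT NDE and T NDE) held 3 libraries from biologically independent repetitions, 12 libraries in all. Total counts ran from 16862953 in T NC replicate 3 to 24467873 in T NC replicate 1, and 17301 of 55487 genes had enough counts to be tested.

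Before any comparison, 3 libraries stood apart by their content of salivary gland transcripts. Bpifa2, a secreted protein of salivary glands, is encoded on mm10 chromosome 2 from 154008265 to 154016079. Scaled to the library total without TMM factors, it reached 25420 CPM in T NDE replicate 3, 19567 CPM in NT NC replicate 3 and 997 CPM in NT NC replicate 2. In the other 9 libraries Bpifa2 lay between 6.66 and 38.1 CPM. Genes of the salivary gland list took 4.09% of all counts in T NDE replicate 3 (95% Wilson interval 4.09% to 4.10%), 2.90% in NT NC replicate 3 (2.89% to 2.90%) and 0.157% in NT NC replicate 2 (0.155% to 0.158%). In the other 9 libraries the share was at most 0.00750%. These intervals cover counting error only. The 3 libraries belonged to both the NDE and the NC arm and to both the T and the NT arm, so that each comparison below contains at least 1 of them. The transcript was measured in every library, and the plot of Bpifa2 by library shows the separation.

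**Figure D1:**
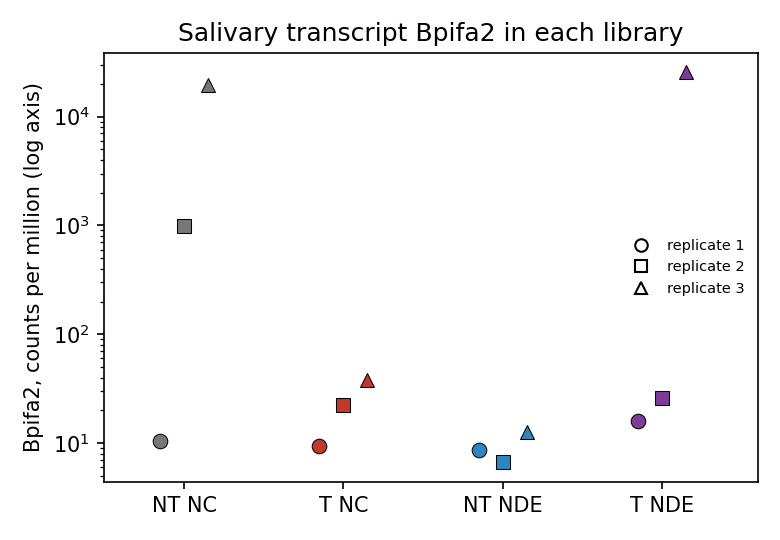
Bpifa2 on a log axis for each of the 12 libraries, in CPM of the library total without TMM factors, grouped by condition. The marker shape gives the replicate number. T NDE replicate 3 at 25420 CPM, NT NC replicate 3 at 19567 CPM and NT NC replicate 2 at 997 CPM lie above the other 9 libraries, which reach at most 38.1 CPM.

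With intact nerves, neutrophil transcripts were higher as a list in nodes of tumour-bearing than of tumour-free mice, a call that was lost with an estimated correlation (adjusted p = 0.0650 with an estimated correlation). Of 15 tested members of the neutrophil list, 14 were higher in T NC than in NT NC. The median log2 fold change was 1.34, and the list's mean log2 CPM was 4.37 ± 0.34 (SD, n = 3) in T NC against 3.13 ± 0.59 (SD, n = 3) in NT NC. Lcn2, the iron-sequestering lipocalin of neutrophil granules, averaged 30.3 ± 8.67 CPM in T NC and 10.1 ± 2.58 CPM in NT NC (SD, n = 3). S100a8, a calcium-binding alarmin, averaged 74.5 ± 23.9 CPM and 24.7 ± 8.49 CPM in the same groups, and Cd177, a neutrophil surface glycoprotein, 11.5 ± 3.43 CPM and 4.28 ± 2.04 CPM. With the preset correlation, genes of immunosuppression and of the pre-metastatic niche, follicular helper T cells and germinal centre B cells were higher as lists as well, and type I interferon response genes lower. None of these calls held with an estimated correlation (adjusted p = 0.243, 0.0874, 0.519 and 0.653 in that order), and the niche and interferon calls were also lost without the 3 salivary libraries (adjusted p = 0.0742 and 0.534).

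Camera, a competitive test of a list against all other genes, called 21 of 51 lists between T NC and NT NC, 16 higher and 5 lower. The neutrophil list led (camera adjusted p = 3.33e-30 with the preset correlation, adjusted p = 0.0650 with an estimated correlation). Of its members 0 passed over all genes, while 11 passed when adjusted over the list alone. Its median was 0.79 without the 3 salivary libraries. The list of niche and immunosuppressive genes had a median of 0.17 over 18 genes (adjusted p = 0.243 with an estimated correlation), with 6 members higher when adjusted over the list alone. That median was 0.31 without T NC replicate 2 and 0.11 without T NC replicate 3. The call was lost without the 3 salivary libraries (median 0.05, adjusted p = 0.0742). All 20 type I interferon genes were lower in T NC, with a median of -0.42 (adjusted p = 0.653 with an estimated correlation) and 0 members passing when adjusted over the list alone. This median was -0.21 without T NC replicate 1, -0.23 without T NC replicate 2, -0.81 without T NC replicate 3 and -0.18 without NT NC replicate 2. The call was lost without the 3 salivary libraries (median -0.09, adjusted p = 0.534).

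Lists of the follicular response were higher in T NC. The 9 follicular helper T cell genes had a median of 0.18 (adjusted p = 0.0874 with an estimated correlation). It was 0.28 without T NC replicate 2 and 0.32 without the 3 salivary libraries, and 3 of the genes passed when adjusted over the list alone. Among these, Il21, the cytokine that drives germinal centre B cells, averaged 4.95 ± 1.47 CPM in T NC and 1.80 ± 1.03 CPM in NT NC (SD, n = 3). Cxcl13, the chemokine that draws B cells into follicles, averaged 230 ± 5.28 CPM and 174 ± 15.6 CPM (SD, n = 3). All 12 germinal centre B cell genes were higher (median 0.33, adjusted p = 0.519 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. The NF-kB and inflammatory cytokine list had a median of 0.24 over 15 genes (adjusted p = 0.278 with an estimated correlation), with 2 members past when adjusted over the list alone. One of its members, the monocyte chemoattractant Ccl2, averaged 7.76 ± 2.38 CPM in T NC and 3.57 ± 1.76 CPM in NT NC. That list's median was 0.12 without T NC replicate 3, 0.11 without NT NC replicate 3, 0.11 without either the 3 or the 2 most salivary libraries and 0.07 with Bpifa2 as a covariate. All 17 oxidative phosphorylation genes were higher (median 0.13, adjusted p = 0.519 with an estimated correlation), and 0 passed when adjusted over the list alone. All 24 cell cycle genes were higher too (median 0.14, adjusted p = 0.736 with an estimated correlation), again with 0 members past when adjusted over the list alone. The cell cycle call was lost and the median negative without NT NC replicate 1 (-0.04, adjusted p = 0.362). The median was 0.07 without T NC replicate 1, 0.24 without NT NC replicate 2, 0.24 without NT NC replicate 3 and 0.71 without the 3 salivary libraries. It was 0.25 without the 2 most salivary libraries and 0.28 with Bpifa2 as a covariate.

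No single gene passed between T NC and NT NC in edgeR (0 of 17301 genes, smallest adjusted p = 0.286). An unadjusted p under 0.05 was found for 1350 genes, where chance gives 865 on average. Genes move together, and the spread of such counts under chance was not estimated here or in the other contrasts, so the excess alone shows no effect. DESeq2 called 40 genes, 29 higher and 11 lower, and limma-voom called 0. Of the DESeq2 calls, 7 of the higher ones were neutrophil list members and 5 of the lower ones belonged to the 51 genes in excess in T NDE replicate 3. Leaving out 1 library gave 0 to 3 edgeR calls (3 without T NDE replicate 3, 2 without T NC replicate 1, 2 without T NC replicate 3 and 1 without T NC replicate 2). Without the 3 salivary libraries, which left NT NC with 1 library, edgeR called 7 genes, 3 higher and 4 lower, among them Socs3 (log2 fold change 1.00) and Il21 (3.01). Besides Lcn2 (log2 fold change 1.59, SE 0.23), the smallest p values belonged to Socs3, a feedback inhibitor of cytokine signalling (0.68, SE 0.11), Mybpc1 (-1.68), Slc15a3 (0.35), the acute-phase protein Hp (1.44), Il1f9 (1.80), H2afx (0.37), Tomm5 (0.40), Ifitm6 (1.35) and Cacna1b (-0.63), all with edgeR adjusted p of 0.286 or more.

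In tumour-bearing mice, nerve inhibition went with lower levels of type I and type II interferon response genes, extracellular matrix genes and neutrophil genes as lists. These calls were lost with an estimated correlation (adjusted p = 0.268, 0.222, 0.222 and 0.222 in that order). All 20 tested type I interferon genes were lower in T NDE than in T NC, with a median log2 fold change of -0.76. Ifit1, an interferon-induced protein that binds foreign RNA, averaged 10.4 ± 2.40 CPM in T NDE and 29.8 ± 18.3 CPM in T NC (SD, n = 3). Oas1a, an antiviral nucleotide synthetase, averaged 11.5 ± 1.16 CPM and 19.5 ± 5.09 CPM (SD, n = 3). Cxcl9, the interferon gamma-induced T cell chemokine, averaged 28.0 ± 3.07 CPM and 55.6 ± 19.9 CPM in the same order. The neutrophil median was -0.90, with Camp, the cathelicidin antimicrobial peptide, at 8.53 ± 2.01 CPM in T NDE and 22.6 ± 9.19 CPM in T NC.

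Camera called 20 of 51 lists between T NDE and T NC, 4 higher and 16 lower. The type I interferon list led (camera adjusted p = 1.74e-21 with the preset correlation, adjusted p = 0.268 with an estimated correlation), with 0 members past the threshold either over all genes or when adjusted over the list alone. Its median was -0.36 without T NC replicate 3. The interferon gamma list had a median of -0.28 over 18 genes (adjusted p = 0.222 with an estimated correlation). Of its members 12 were lower when adjusted over the list alone, among them the guanylate-binding protein genes Gbp2 (-0.40) and Gbp6 (-0.58). Of 19 extracellular matrix genes, 18 were lower (median -0.39, adjusted p = 0.222 with an estimated correlation) and 10 passed when adjusted over the list alone. These included the matricellular protein gene Sparc (226 ± 25.3 CPM in T NDE and 306 ± 25.1 CPM in T NC) and the proteoglycan gene Bgn (174 ± 9.92 CPM and 221 ± 41.5 CPM; SD, n = 3). For neutrophils (adjusted p = 0.222 with an estimated correlation), 7 of 15 members were lower when adjusted over the list alone.

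Lists of T cells and cytotoxic lymphocytes had smaller negative medians. All 13 pan T cell genes were lower in T NDE (median -0.17, adjusted p = 0.269 with an estimated correlation), and 1 passed when adjusted over the list alone. The examples Cd6, Trac and Cd5 had log2 fold changes of -0.34, -0.27 and -0.30. All 13 cytotoxic lymphocyte genes were lower (median -0.26, adjusted p = 0.222 with an estimated correlation), with 0 passing when adjusted over the list alone, including the granule proteins Nkg7 (-0.26) and Prf1 (-0.20). The 13 genes of MHC class I and its peptide loading were lower as well (median -0.15, adjusted p = 0.269 with an estimated correlation, 0 past when adjusted over the list alone). Their median was -0.09 without T NC replicate 3. The niche and immunosuppressive list had a median of -0.31 (adjusted p = 0.222 with an estimated correlation), with 4 of 18 lower when adjusted over the list alone. Its median was -0.50 without T NDE replicate 3, -0.47 without T NC replicate 2, -0.14 without T NC replicate 3 and -0.50 without either the 3 or the 2 most salivary libraries.

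Single genes did not pass between T NDE and T NC in edgeR (0 of 17301 genes, smallest adjusted p = 0.149), with 1008 genes at an unadjusted p under 0.05 (865 by chance). DESeq2 called 44 genes (23 higher and 21 lower, 6 of the higher ones among the 51 genes in excess in T NDE replicate 3) and limma-voom 0. Leaving out NT NDE replicate 3 or T NC replicate 2 gave 1 edgeR call, and leaving out the 3 salivary libraries gave 1, the macrophage lectin gene Chil3 (-1.29). The smallest p belonged to Il9r, the receptor of the type 2 cytokine interleukin 9, at 72.2 ± 2.47 CPM in T NDE and 46.5 ± 3.26 CPM in T NC (log2 fold change 0.64, SE 0.095, edgeR adjusted p = 0.149; SD over n = 3). Next were Sox13, a transcription factor of gamma delta T cells (1.00), Olfm4 (-3.08), the gamma delta T cell receptor segment Tcrg-V6 (2.41), Spock2 (0.86), Kcnk1 (2.05), Art2b (-0.44), Gm4617 (-0.62), Arnt2 (1.03) and Maf (0.31), with edgeR adjusted p from 0.185 to 0.272.

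Without a tumour, nerve inhibition also went with lower type I interferon response genes and higher follicular dendritic cell genes as lists. Both calls were lost with an estimated correlation (adjusted p = 0.422 and 0.126 with an estimated correlation). All 20 type I interferon genes were lower in NT NDE than in NT NC (median log2 fold change -0.73). Ifit1 averaged 16.7 ± 2.34 CPM against 44.6 ± 10.4 CPM, and Mx1, an antiviral GTPase, 47.0 ± 3.52 CPM against 89.5 ± 15.5 CPM (SD, n = 3). Cxcl13 averaged 279 ± 15.4 CPM in NT NDE and 174 ± 15.6 CPM in NT NC, and Coch, a follicular dendritic cell product, 17.4 ± 2.81 CPM and 9.14 ± 1.45 CPM. Of 12 follicular dendritic cell genes, 11 were higher (median 0.27). Socs3 averaged 127 ± 6.06 CPM in NT NDE and 73.9 ± 12.8 CPM in NT NC, and Slfn1, a growth-regulating gene of quiescent T cells, 67.3 ± 0.866 CPM and 102 ± 7.87 CPM.

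Camera called 20 of 51 lists between NT NDE and NT NC, 15 higher and 5 lower. For the type I interferon list (camera adjusted p = 9.33e-19 with the preset correlation, adjusted p = 0.422 with an estimated correlation), 9 members were lower when adjusted over the list alone. The median was -0.38 without the 3 salivary libraries. The interferon gamma list had a median of -0.15 (adjusted p = 0.542 with an estimated correlation), or -0.24 without NT NC replicate 3 and -0.24 without the 2 most salivary libraries. When tested within the list, 4 of 18 members were lower when adjusted over the list alone, with Gbp4 at -0.48 and the GTPase gene Igtp at -0.59. For follicular dendritic cells (adjusted p = 0.126 with an estimated correlation), 3 members were higher when adjusted over the list alone. The median was 0.15 without the 3 salivary libraries. The follicular helper T cell list had a median of 0.14 (adjusted p = 0.102 with an estimated correlation), with 4 of 9 higher when adjusted over the list alone, among them the transcription regulators Maf (0.35) and Tox2 (0.45). That median was 0.07 without NT NC replicate 1, 0.24 without NT NC replicate 3, 0.39 without the 3 salivary libraries and 0.23 without the 2 most salivary ones. Fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 3 lists in this comparison and 0 in each of the others. These were follicular dendritic cells, follicular helper T cells, and lymphotoxin and lymphoid chemokines, each with a fry adjusted p of 0.0409, and Cxcl13 is a member of all 3. The median of the last list was 0.19 (adjusted p = 0.126 with an estimated correlation) with 1 of 14 higher when adjusted over the list alone.

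Among the other lists higher in NT NDE, neutrophils had a median of 0.80 (adjusted p = 0.421 with an estimated correlation) with 5 of 15 members higher when adjusted over the list alone. Lcn2 averaged 18.8 ± 2.33 CPM against 10.1 ± 2.58 CPM (SD, n = 3). This call was lost without the 3 salivary libraries (median 0.30, adjusted p = 0.545). All 12 germinal centre B cell genes were higher (median 0.50, adjusted p = 0.542 with an estimated correlation), with 0 passing when adjusted over the list alone. The median was 0.23 without NT NDE replicate 3, 0.31 without NT NC replicate 3 and 0.30 without the 2 most salivary libraries. All 24 cell cycle genes were higher (median 0.25, adjusted p = 0.546 with an estimated correlation), with 0 passing when adjusted over the list alone. That call was lost without NT NC replicate 1 (median 0.06, adjusted p = 0.328). The median was 0.11 without NT NDE replicate 3, 0.38 without NT NC replicate 3, 0.79 without the 3 salivary libraries and 0.42 with Bpifa2 as a covariate. The niche and immunosuppressive list had a median of 0.21 (adjusted p = 0.433 with an estimated correlation) with 1 of 18 higher when adjusted over the list alone. It was 0.32 without NT NC replicate 1 and 0.34 with Bpifa2 as a covariate, and its call was lost without the 3 salivary libraries (0.21, adjusted p = 0.195).

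Between NT NDE and NT NC, edgeR called 0 of 17301 genes (smallest adjusted p = 0.0788), with 1796 genes at an unadjusted p under 0.05 (865 by chance). DESeq2 called 138 (56 higher and 82 lower, 11 of the lower ones among the 51 genes in excess in T NDE replicate 3) and limma-voom 0. Fitted on the 6 libraries of these groups alone, edgeR called 37 genes, 15 higher and 22 lower. Without the 3 salivary libraries, NT NC held only replicate 1, the library without which the cell cycle list lost its call in this comparison. The cell cycle median of 0.79 in that fit therefore rests on 1 library of NT NC. Leaving out 1 library gave up to 7 calls (7 without T NC replicate 3, 6 without T NDE replicate 1, 3 without T NDE replicate 3 and 1 without NT NDE replicate 2, T NC replicate 1 or NT NC replicate 2). Camera called 12 lists without NT NDE replicate 3. In the fit of all 12 libraries, Slfn1 (log2 fold change -0.60, SE 0.086) and Socs3 (0.78, SE 0.11) had the smallest p, each with edgeR adjusted p = 0.0788. They were followed by Sp4 (-0.34), Gm30948 (-1.21), Gm14085 (-0.70), Cxcl13 (0.68), Maf (0.35), Snx22 (0.70), Apol7e (-0.52) and Coch (0.93), each with edgeR adjusted p = 0.101.

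**Figure D2:**
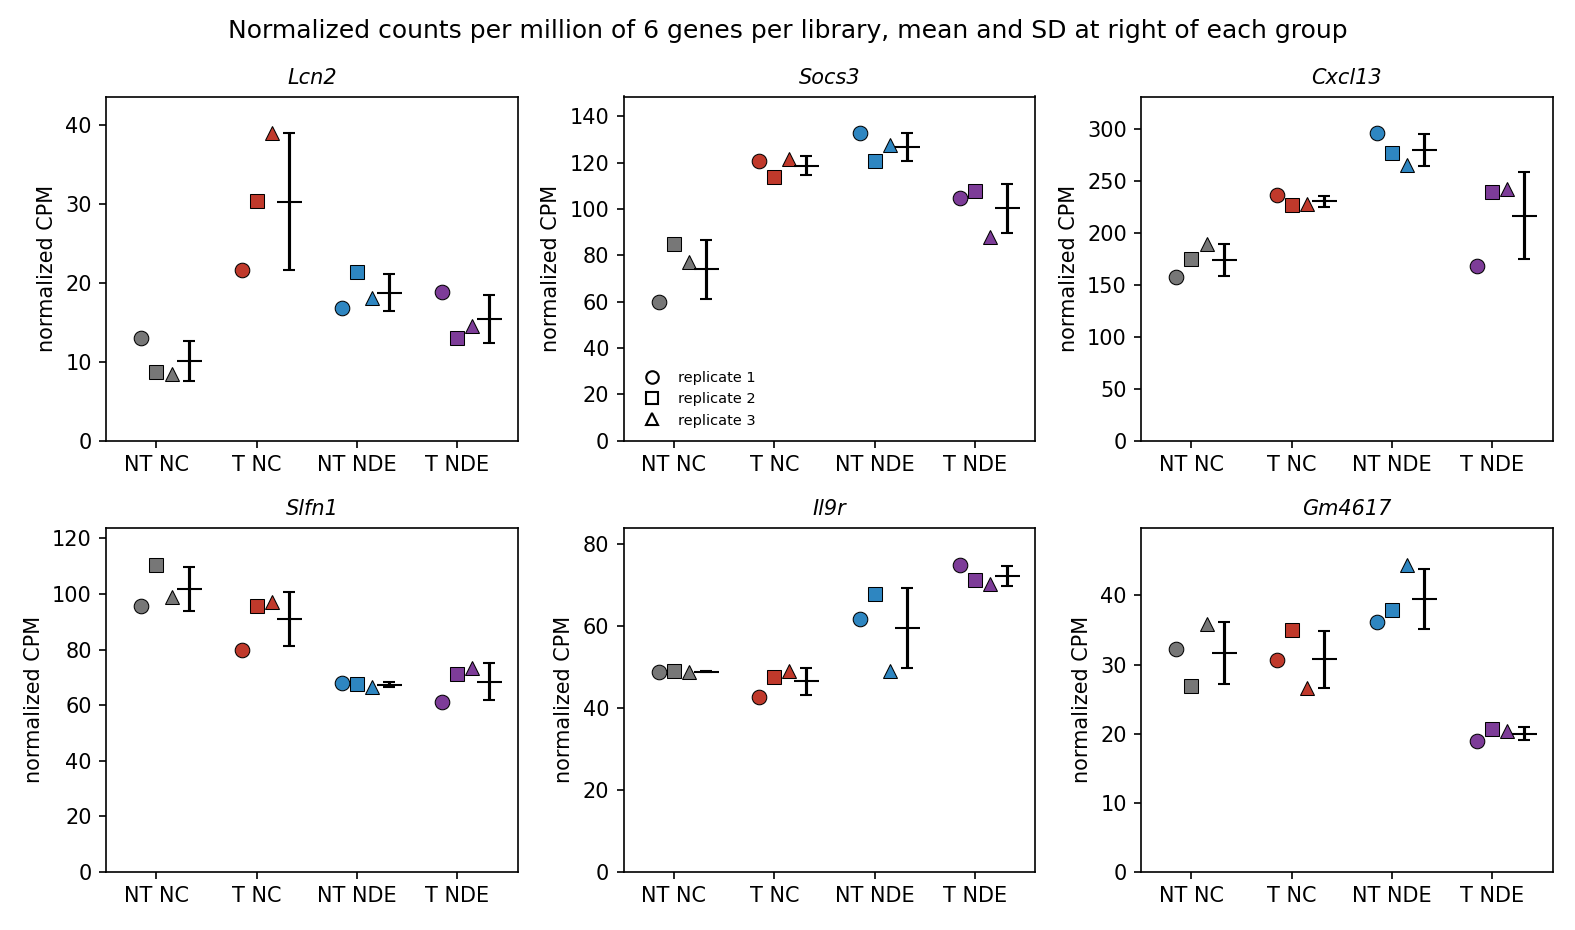
Normalized counts (CPM) of Lcn2, Socs3, Cxcl13, Slfn1, Il9r and Gm4617 in each of the 12 libraries, with the group mean and SD (n = 3) at the right of each group and the marker shape giving the replicate number. Lcn2 averaged 30.3 CPM in T NC and 10.1 CPM in NT NC, and Gm4617 averaged 20.02 CPM in T NDE and 39.5 CPM in NT NDE.

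With nerves inhibited, the sinus macrophage, complement and matrix lists had negative medians for tumour-bearing against tumour-free nodes, and their calls were lost with an estimated correlation (adjusted p = 0.610, 0.513 and 0.610 in that order). Sinus macrophage scores of the groups overlapped, at 6.01, 6.10 and 6.82 in T NDE and 6.53, 6.54 and 6.63 in NT NDE (mean log2 CPM). Siglec1, the sialoadhesin of subcapsular and medullary sinus macrophages, averaged 202 ± 51.4 CPM in T NDE and 295 ± 11.1 CPM in NT NDE, and C1qc, a chain of the first complement component, 117 ± 18.3 CPM and 156 ± 4.59 CPM (SD, n = 3). Pdpn, the podoplanin gene of lymphatic endothelium and fibroblastic reticular cells, averaged 7.10 ± 0.914 CPM and 10.4 ± 0.350 CPM. Tagln, a smooth muscle gene, averaged 68.6 ± 7.65 CPM in T NDE and 46.3 ± 4.34 CPM in NT NDE.

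A single gene passed in this comparison. Gm4617 fell by 0.98 on the log2 scale (SE 0.12, edgeR adjusted p = 0.0133), from 39.5 ± 4.35 CPM in NT NDE to 20.02 ± 0.909 CPM in T NDE, with 31.6 ± 4.49 CPM in NT NC and 30.7 ± 4.16 CPM in T NC (SD, n = 3). Gm4617 (ENSMUSG00000096544) is annotated as a processed pseudogene at mm10 chromosome 3 from 124385667 to 124385997 on the plus strand. All 331 of its bases match the transcript of the prothymosin gene Ptma (99.1% identity over 334 aligned bases, gaps included). Its count is therefore uncertain, because reads could be divided between the copies. Ptma itself averaged 980.1 CPM in T NDE and 994.6 CPM in NT NDE (log2 fold change -0.02). The Gm4617 call was lost without T NDE replicate 1 (-0.94), without T NDE replicate 2 (-1.003), without NT NDE replicate 3 (-0.89) and with Bpifa2 as a covariate (-1.01).

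Between T NDE and NT NDE, 641 genes had an unadjusted p under 0.05, fewer than the 865 that chance gives. DESeq2 called 17 genes, 12 higher and 5 lower, and limma-voom called 1. Of the higher DESeq2 calls, 10 were among the 51 genes in excess in T NDE replicate 3. Without T NDE replicate 3 edgeR called 4 genes, without NT NDE replicate 2 it called 2, without the 2 most salivary libraries 4, and without the 3 salivary libraries 28, 1 higher and 27 lower. Of these 28, 4 were sinus macrophage genes, and the lower ones included Siglec1 (-0.76), the lymph-filtering C-type lectin gene Cd209b (-0.66) and the scavenger receptor gene Marco (-0.60). After Gm4617 the smallest p values in all 12 libraries were those of Flrt3 (-0.72), Gm2260 (-5.04), Lipg (-0.88), Tagln (0.57), Mid1 (0.99), G530011O06Rik (1.83), Pdpn (-0.55), Gm48065 (-2.39) and Armcx4 (-0.68), with edgeR adjusted p of 1.00 after rounding.

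Camera called 14 of 51 lists between T NDE and NT NDE, 3 higher and 11 lower, all lost with an estimated correlation. Complement had a median of -0.25 over 15 genes (adjusted p = 0.513 with an estimated correlation), or -0.17 without T NDE replicate 1 and -0.38 without T NDE replicate 3. Extracellular matrix genes had a median of -0.24 (adjusted p = 0.610 with an estimated correlation), or -0.14 without NT NDE replicate 3, and type I interferon genes -0.42 (adjusted p = 0.791 with an estimated correlation). In each of these lists 0 members passed when adjusted over the list alone. Sinus macrophage genes had a median of -0.26 over 14 genes (adjusted p = 0.610 with an estimated correlation) with 2 lower when adjusted over the list alone. That median was -0.09 without T NDE replicate 1, -0.57 without T NDE replicate 3, and -0.56 without either the 3 or the 2 most salivary libraries. Monocyte genes had a median of -0.27 over 12 genes (adjusted p = 0.513 with an estimated correlation), or -0.41 without T NDE replicate 3, with 1 lower when adjusted over the list alone. Lymphatic endothelial genes had a median of -0.22 over 12 genes (adjusted p = 0.513 with an estimated correlation), with 1 lower when adjusted over the list alone. That value was -0.09 without T NDE replicate 1, -0.50 without T NDE replicate 3, -0.50 without either the 3 or the 2 most salivary libraries and -0.39 with Bpifa2 as a covariate. The niche and immunosuppressive list had a median of -0.27 (adjusted p = 0.513 with an estimated correlation), with 0 past when adjusted over the list alone. It was -0.44 without T NDE replicate 3 and -0.44 without either the 3 or the 2 most salivary libraries. Follicular dendritic cell genes had a median of -0.15 (adjusted p = 0.513 with an estimated correlation), with 0 past when adjusted over the list alone. The median was -0.29 without T NDE replicate 2, with no call without T NDE replicate 1 (-0.17, adjusted p = 0.0645). Fibroblastic reticular cell genes had a median of -0.13 and a mean of 0.08 (adjusted p = 0.610 with an estimated correlation), so median and mean differed in sign. Of these genes, 3 of 15 were lower when adjusted over the list alone.

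The interaction compared the effect of nerve inhibition in tumour-bearing mice with that in tumour-free mice. For neutrophil genes this difference was negative for all 15 members, with a median of -1.51 (adjusted p = 0.0990 with an estimated correlation). The list had a median of -0.90 for T NDE against T NC and 0.80 for NT NDE against NT NC. For Lcn2 the difference was -1.87 (SE 0.32) and for Cd177 -1.97 (SE 0.42), and for Mmp9, a matrix-degrading neutrophil protease, -0.94 (SE 0.24). Cxcl13 (-0.77) and Mfge8 (-0.43), genes of follicular dendritic cells, and Ccl2 (-1.73) and Il1b (-1.36), inflammatory cytokine genes, had differences of the same sign. Tcrg-V6 (2.88) and the potassium channel genes Kcnt1 (3.01) and Kcnk1 (2.48) had positive differences.

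Camera called 19 of 51 lists for the interaction, 2 higher and 17 lower. The neutrophil list (camera adjusted p = 2.78e-24 with the preset correlation, adjusted p = 0.0990 with an estimated correlation) had 9 members lower when adjusted over the list alone. Its median was -0.96 without the 3 salivary libraries. The niche and immunosuppressive list had a median of -0.64 (adjusted p = 0.0990 with an estimated correlation), with 5 lower and 1 higher when adjusted over the list alone. It was -0.41 without T NC replicate 1 and -0.42 without T NC replicate 3. For extracellular matrix genes the median was -0.42 (adjusted p = 0.303 with an estimated correlation) with 0 past when adjusted over the list alone. For complement it was -0.29 (adjusted p = 0.303 with an estimated correlation) with 2 lower, or -0.45 without T NDE replicate 3. Follicular dendritic cell genes had a median of -0.39 (adjusted p = 0.129 with an estimated correlation), or -0.25 without T NDE replicate 1. Of these genes, 6 of 12 were lower when adjusted over the list alone. Follicular helper T cell genes had a median of -0.12 (adjusted p = 0.0990 with an estimated correlation), with 1 lower when adjusted over the list alone. The value was -0.20 without T NDE replicate 2, -0.22 without T NC replicate 2 and -0.19 with Bpifa2 as a covariate. The NF-kB and cytokine list had a median of -0.24 (adjusted p = 0.303 with an estimated correlation) with 1 lower when adjusted over the list alone. It moved to -0.15 without NT NC replicate 2 and -0.14 without the 3 salivary libraries. Fibroblastic reticular cell genes had a median of -0.21 (adjusted p = 0.303 with an estimated correlation) with 4 lower when adjusted over the list alone. That median was -0.07 without T NDE replicate 1, -0.36 without T NDE replicate 3, -0.05 without NT NDE replicate 2, -0.09 without T NC replicate 1, -0.13 without T NC replicate 2 and -0.07 without NT NC replicate 2.

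For the interaction edgeR called 0 of 17301 genes (smallest adjusted p = 0.321), with 1230 genes at an unadjusted p under 0.05 (865 by chance). DESeq2 called 43 (21 higher and 22 lower) and limma-voom 0. Of the 21 higher DESeq2 calls, 16 were among the 51 genes in excess in T NDE replicate 3, and 5 of the lower ones were neutrophil list members. Leaving out T NC replicate 2 or NT NC replicate 1 gave 2 edgeR calls, leaving out NT NC replicate 2 gave 1, and leaving out the 3 salivary libraries gave 3, among them Socs3 (-1.24). In all 12 libraries Socs3 had the smallest p (-1.02, SE 0.15, edgeR adjusted p = 0.321). It was followed by Gm4617 (-0.94), Lcn2, Tcrg-V6, Kcnt1, Pdpn (-0.96), Slc15a3 (-0.45), Dtx1 (-0.68), Kcnk1 and Ifitm2 (-1.05), with edgeR adjusted p from 0.457 to 0.501.

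**Figure D3:**
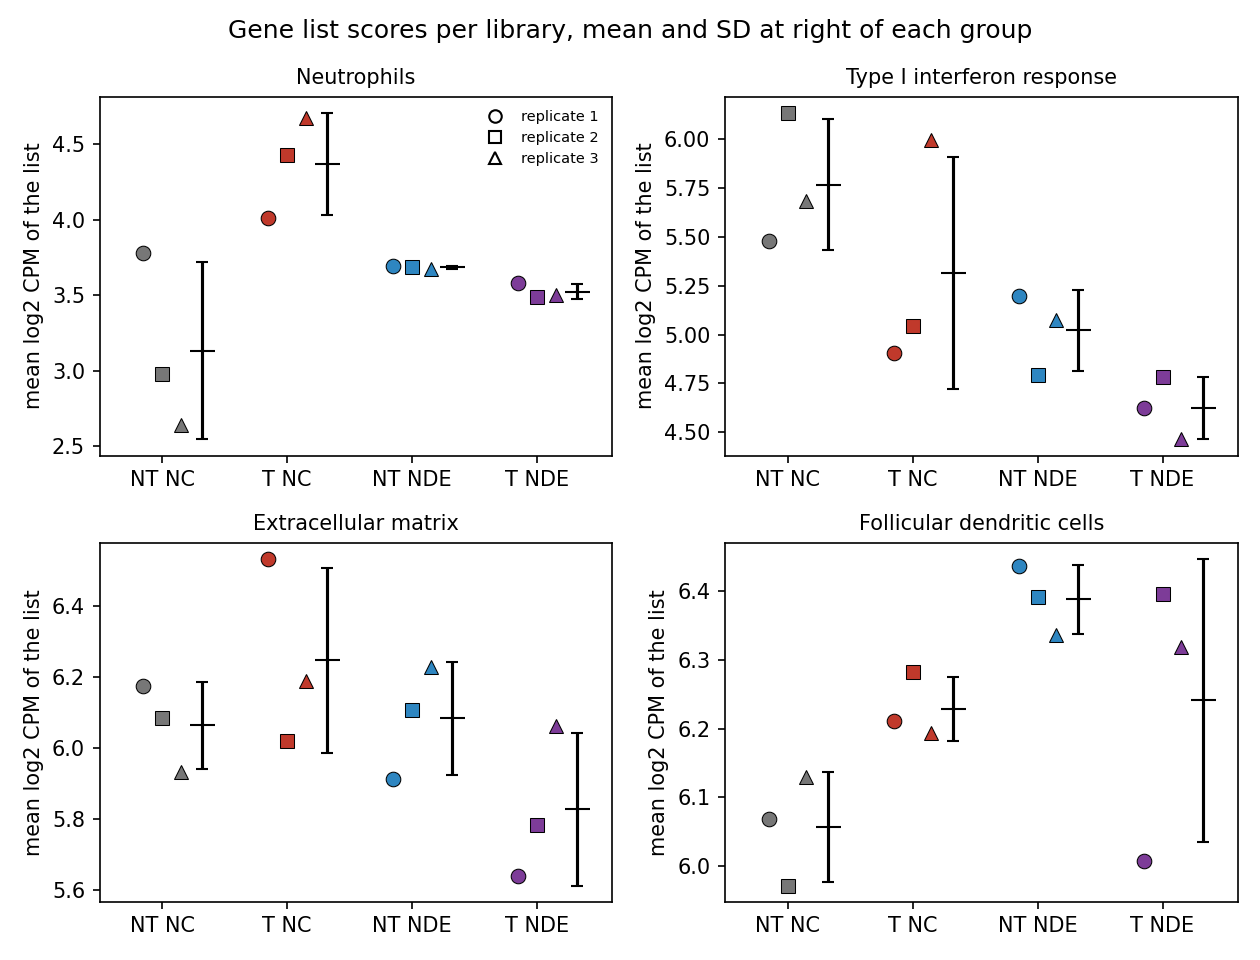
Mean log2 CPM of the members of 4 gene lists (neutrophils, type I interferon response, extracellular matrix and follicular dendritic cells) in each of the 12 libraries, with group mean and SD (n = 3) at the right of each group. The neutrophil score was 4.37 in T NC, 3.13 in NT NC, 3.68 in NT NDE and 3.52 in T NDE.

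**Figure D4:**
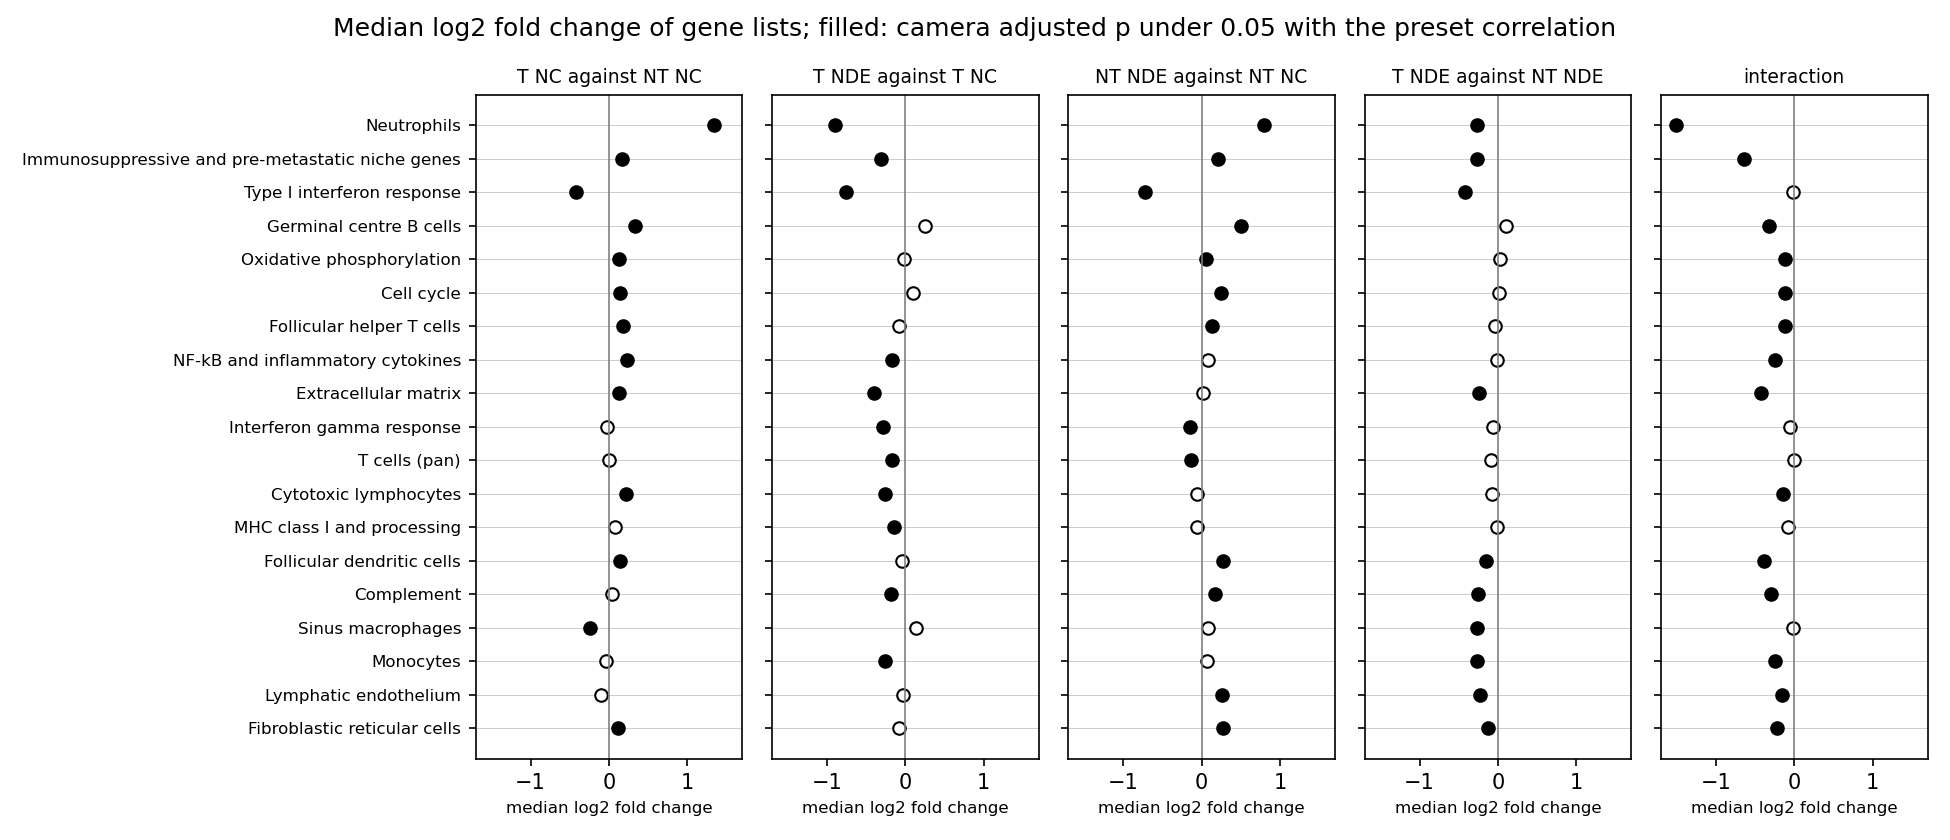
Median log2 fold change of 19 gene lists in the 4 comparisons of groups and the interaction, with filled points where camera's adjusted p with the preset correlation was under 0.05 and open points elsewhere. The neutrophil median was 1.34 for T NC against NT NC and -0.90 for T NDE against T NC.

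Across the 17301 genes, fold changes of T NDE against T NC ran opposite to those of T NC against NT NC (Pearson r = -0.785 across genes, which are not independent replicates). Both use the T NC libraries with opposite sign, and simulated unchanged groups sharing those libraries gave r = -0.499. The covariance was -0.191 against a simulated -0.0541 (SD 0.00545 over 20 simulations), a difference of -0.137. Without the 3 salivary libraries it was -0.0703 against -0.0468 (SD 0.00413 over 10 simulations), a difference of -0.0235. The correlation was then r = -0.297 against a simulated -0.285 (SD 0.0224), so by r no excess was left in this pair. T NDE against T NC and NT NDE against NT NC, which share no library, had r = -0.559 with 12 libraries. With the 9 remaining libraries their covariance was 0.00216 against a simulated -0.000507 (SD 0.00250), so no excess was left in this pair. T NC against NT NC and T NDE against NT NDE, which also share no library, had -0.00524 against -0.00265 (SD 0.00279). T NC against NT NC and NT NDE against NT NC, which share NT NC, had 0.228 against a simulated 0.182 (SD 0.0104). By r this pair had 0.760 against a simulated 0.799 (SD 0.0104), so no excess was left by that measure. With 9 libraries, a covariance beyond the simulated one was thus not particular to the pair sharing T NC, and neither pair had an excess by r. The simulations drew genes independently, so their SDs may be too narrow for genes that move together. The T NC group was too small to be divided, so part of the excess covariance in the pair sharing T NC may come from those shared libraries.

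Receptors through which nociceptor mediators act did not pass in any contrast. Calcrl, the receptor of the neuropeptide CGRP, averaged 71.9 ± 4.96 CPM in NT NC, 66.5 ± 1.91 CPM in T NC, 65.1 ± 7.22 CPM in NT NDE and 64.0 ± 4.55 CPM in T NDE (SD, n = 3). Its co-receptor Ramp1 averaged 21.2 ± 3.93, 21.6 ± 2.22, 20.4 ± 2.40 and 18.8 ± 1.04 CPM in the same order. Tacr1, the substance P receptor, averaged 3.17 ± 0.576, 3.996 ± 0.433, 3.99 ± 0.157 and 3.21 ± 0.568 CPM. The smallest edgeR adjusted p of these 3 genes over the 5 contrasts was 0.573, for Calcrl in NT NDE against NT NC.

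Several melanocyte genes held few counts in all groups, among them pigment genes of the melanoma lineage. Tyrp1 had 11 counts in T NC, all in 1 library, 5 in T NDE, and 0 in NT NC and NT NDE, where 0 counts allow up to 0.0485 and 0.0529 CPM (counting error only). Dct had 3 counts in T NC, 5 in T NDE, 1 in NT NDE and 0 in NT NC. Mlana had 4 counts in T NC, 4 in NT NC, 2 in T NDE and 0 in NT NDE, and Slc45a2 had 4 in T NC, 3 in T NDE and 0 in NT NC and NT NDE. Tyrp1, Dct, Mlana and Slc45a2 were too low to be tested, and all their T NC counts were in T NC replicate 3. In T NDE, all counts of Dct and Slc45a2 and 4 of the 5 of Tyrp1 were in T NDE replicate 2. Slc24a5, too low to be tested, had 20 counts in T NDE (0.342 ± 0.0400 CPM), 4 in NT NDE (0.0708 ± 0.0613 CPM), 9 in T NC (0.148 ± 0.0575 CPM) and 5 in NT NC (0.0938 ± 0.162 CPM; SD, n = 3). Its T NDE libraries did not overlap those of NT NDE. Pmel averaged 0.759 ± 0.238 CPM in T NC and 0.588 ± 0.0851 CPM in NT NC, and 0.808 ± 0.159 CPM in T NDE and 0.612 ± 0.256 CPM in NT NDE (SD, n = 3), with edgeR adjusted p of 0.842 for T NC against NT NC. Tyr averaged 0.403 ± 0.111 CPM in T NC and 0.819 ± 0.0932 CPM in NT NC. Summed over Pmel, Dct, Tyr, Tyrp1 and Mlana, libraries ranged from 1.33 to 1.79 CPM in T NDE and 0.896 to 1.24 CPM in NT NDE, and from 0.817 to 2.49 CPM in T NC and 1.33 to 1.59 CPM in NT NC. Other melanocyte genes were well above these levels in each group: Mitf averaged from 8.09 CPM in T NC to 8.80 CPM in NT NDE, Trpm1 from 3.55 CPM in T NC to 4.20 CPM in NT NC, and Gpnmb from 2.90 CPM in T NDE to 5.40 CPM in T NC. Sox10 had 254 of its 255 T NDE counts in 1 library and 122 of its 136 NT NC counts in 1 library, the libraries with the most Bpifa2.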

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

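All tests of the salivary pattern, the splits of gene counts, the blood, salivary, adipose and single-library tests, the permutation test and the salivary alternatives were chosen after the results they concern were seen, whereas the second lists and the splits of list counts were set before theirs.

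The interaction test of whether nerve inhibition acted differently with and without a tumour singled out 19 lists, each past camera's threshold with the preset correlation and none with an estimated one. The medians of the difference were -1.51 for neutrophils, 16.09 for salivary gland genes, -0.64 for niche and immunosuppressive genes, -0.42 for extracellular matrix, -0.29 for complement, -0.39 for follicular dendritic cells, -0.12 for follicular helper T cells, -0.21 for fibroblastic reticular cells and -0.24 for NF-kB and inflammatory cytokines. For the remaining lists the estimated-correlation p is given beside the median: monocytes -0.24 (adjusted p = 0.451 with an estimated correlation), circadian clock 0.19 (adjusted p = 0.303), cell cycle -0.12 (0.849), germinal centre B cells -0.32 (0.659), cholesterol synthesis -0.13 (0.765), lymphatic endothelium -0.16 (0.571), oxidative phosphorylation -0.12 (0.724), ribosomal proteins -0.0836 (0.849), immediate early genes -0.11 (0.303) and cytotoxic lymphocytes -0.15 (0.451).

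Other divisions of the same libraries gave as many list calls, so the number of called lists by itself cannot exclude chance. For the interaction, 33 of 100 drawn splits called at least as many lists as the real 19, and the highest other split called 28. For 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. There, the real counts of lists were 21, 20, 20 and 14 in the order T NC against NT NC, T NDE against T NC, NT NDE against NT NC and T NDE against NT NDE, the highest other splits gave 27, 25, 20 and 23, and 5, 4, 3 and 4 of the 10 splits reached the real count. For gene counts the real values were 0, 0, 0 and 1 and the highest other splits gave 1, 0, 0 and 0. The real count was reached by 10, 10, 10 and 1 of the 10 splits, and for the interaction a real count of 0 genes by 100 of 100, with 1 as the highest other. A count of 0 is reached by any split, so the shares for counts of 0 say nothing about chance.

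Salivary gland transcripts were far above the other libraries in T NDE replicate 3, NT NC replicate 3 and NT NC replicate 2. If salivary gland tissue had been taken along with these nodes, the same genes should be in excess in each, and the 51 genes at least 50-fold above the other 9 libraries in T NDE replicate 3 had excesses that correlated across genes with r = 0.949 with those in NT NC replicate 3. Their median log2 excess was 6.97, 6.27 and 2.77 in the 3 libraries, and 51 and 48 of them were raised at least 2-fold in NT NC replicates 3 and 2. Part of the r may be built in, because both excesses were measured against the same 9 libraries. The genes were also chosen by their excess in T NDE replicate 3. The tumour or the nerve inhibition as the whole source is argued against by NT NC, whose mice had neither, since the lower of the excesses in its replicates 2 and 3 was 2.77, a value already known when this test was chosen. Admixed tissue is the candidate explanation that the values fit, and it does not say which other genes it shifts.

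The neutrophil list was higher in T NC than in the other groups, with library scores of 4.01, 4.43 and 4.67 in T NC, 3.78, 2.98 and 2.64 in NT NC, and 3.49 to 3.69 in the 6 NDE libraries. A larger amount of blood in the node as the whole cause is argued against. The largest ratio of the haemoglobin transcript Hbb-bs between any T NC and any NT NC library was 1.38, while the list's median corresponds to 2.53-fold. This test replaced an undecided one on the Hbb-bs fold change. It cannot decide whether the same amount of blood held more neutrophils, because Hbb-bs does not count them. Salivary and adipose admixture as the whole cause are argued against by medians of 1.17 with the Bpifa2 covariate and 1.29 with the adipocyte score as a covariate (the adipocyte list itself had a median of 1.13, adjusted p = 0.736 with an estimated correlation), and the choice of members by a second list of 18 other tested neutrophil genes with an interaction median of -0.66 (camera p = 3.11e-07, or p = 0.00667 with an estimated correlation). One NT NC library without a salivary signal scored 3.78, above the NDE libraries, so the comparison with NT NC rests partly on the salivary ones (median 0.79 without all 3). A response of neutrophils to the tumour that needs intact nociceptors may be a hypothesis for this pattern, but no test here decides it, and neutrophil counts in nodes of other mice of the 4 groups would.

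Type I interferon genes were lower as a list with nerve inhibition, with and without a tumour, calls that were lost with an estimated correlation (adjusted p = 0.268 and 0.422 with an estimated correlation). Library scores were 4.62, 4.78 and 4.46 in T NDE, 4.91, 5.04 and 5.996 in T NC, 5.198, 4.80 and 5.07 in NT NDE, and 5.48, 6.14 and 5.69 in NT NC. A single library as the whole cause is argued against, as the weakest median of T NDE against T NC without 1 library was -0.36 (without T NC replicate 3), and so is salivary admixture, with a median of -0.65 for NT NDE against NT NC with the covariate, although it was -0.38 without the 3 salivary libraries (-0.73 with all). The choice of members is argued against by medians of -0.28 and -0.32 for a second list of 22 genes, 1 of them shared with a fixed list, which did not pass with an estimated correlation (p = 0.0521 and 0.0901). An exact permutation of NDE and NC labels within T and within NT gave p = 0.005 for this list and for the second list, the smallest that 400 splits can give, but adjusted over 51 lists it was 0.255, which a single list at that minimum cannot improve on, so an effect of nerve inhibition (differences of -0.69 within T and -0.75 within NT) stays open.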

How the results depend on the processing

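The fits without salivary libraries and with the Bpifa2 covariate were chosen after seeing the data, and the others before. Counts of genes past the threshold changed with the tool, the filter and the libraries kept. In the order T NC against NT NC, T NDE against T NC, NT NDE against NT NC, T NDE against NT NDE and interaction, the edgeR counts of 0, 0, 0, 1 and 0 became 40, 44, 138, 17 and 43 with DESeq2, 4, 12, 43, 1 and 1 with no filter, and 7, 1, 33, 28 and 3 without the 3 salivary libraries. With limma-voom they stayed at 0, 0, 0, 1 and 0. The fit of NT NDE and NT NC alone gave 37, and T NDE against NT NDE had 4 without the 2 most salivary libraries and 0 with the covariate. Leaving out each library gave 0 to 3, 0 to 1, 0 to 7, 0 to 4 and 0 to 2. The cause of these changes was not tested, except that a left-out library lowers the group minimum of the filter and so adds low genes.

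The replicate numbers did not pair the libraries: of 18 same-numbered pairs 3 had a correlation of deviations over 0.1 (range -0.133 to 0.517), and in 14 of 36 cases a library correlated best with its own number. With the replicate block the counts were 0, 0, 3, 3 and 1. Called lists numbered 21, 20, 20, 14 and 19 with the preset correlation, 0 in each contrast with an estimated correlation, and 0, 0, 3, 0 and 0 with fry. Leaving out each library gave 15 to 23, 20 to 25, 12 to 21 (12 without NT NDE replicate 3), 11 to 21 and 17 to 22 called lists.

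The covariance of fold changes, -0.191, was -0.739 with no filter, -0.147 with a stricter filter, -0.155 with the replicate block, -0.0703 and -0.0499 without the 3 and the 2 most salivary libraries and -0.0679 with the salivary covariate. With 1 library left out it ran from -0.404 (without T NC replicate 2) to -0.0534 (without T NDE replicate 3). Directions turned for the cell cycle list in T NC against NT NC, -0.0440 without NT NC replicate 1 and otherwise positive (0.243 without NT NC replicate 3), and for Arg1 in T NDE against NT NDE, 3.602 with 12 libraries and 4.57 without NT NDE replicate 2 but -0.15 without T NDE replicate 3, -0.14 without the 3 and -0.14 without the 2 most salivary libraries, and -0.54 with the covariate. The next totals join the fold changes of single genes with the counts of called lists in each contrast. Of 3744 such values under alternatives (157 results), 3596 were labelled the same, 15 weaker, 129 stronger and 4 reversed. For a gene, weaker or stronger meant a lost or gained call, and for a count of lists a clearly lower or higher count. Gm4617 was the only gene with a call to lose. Of 952 values of 40 list results (19 different lists), 945 kept direction and side of the threshold and 6 lost a call. These 952 values all used camera with the preset correlation. With an estimated correlation, which they leave out, all 40 list results lost their call. For the receptor genes, the gene not reported here included, group means of CPM were compared without a test. All 128 of these values moved by less than the SD of the group. Leaving out 1 library of 3 cannot move a mean by as much as that SD, whatever the values. For those alternatives the outcome was fixed in advance and does not show that the means are stable. Depth limits Tyrp1, Dct, Mlana and Slc45a2, which held few counts.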

Other observations

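The gamma delta T cell list and its test were set before the values of its members were seen, but after related genes had been noticed among the smallest p values, and the genes from DESeq2 and from fits with fewer libraries were picked after their values were seen.

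In T NDE against T NC, lists with higher genes were those of blood and high endothelial venules, the circadian clock and glucocorticoid response. Of 15 endothelial genes 13 were higher (median 0.20, adjusted p = 0.432 with an estimated correlation) and 3 passed when adjusted over the list alone, with the vascular growth factor receptor Flt1 at 49.7 ± 5.54 CPM in T NDE and 33.9 ± 5.57 CPM in T NC (SD, n = 3). Of 16 clock genes 14 were higher (median 0.21, adjusted p = 0.268 with an estimated correlation), 0 of them past when adjusted over the list alone, with the clock repressor gene Nr1d1 at 28.2 ± 6.06 CPM and 21.3 ± 2.45 CPM. Clock scores (mean log2 CPM) overlapped, from 4.41 to 4.67 in T NDE and from 4.18 to 4.45 in T NC. Of 12 glucocorticoid-responsive genes 10 were higher (median 0.28, adjusted p = 0.414 with an estimated correlation), 0 past when adjusted over the list alone, with Zbtb16 at 0.98 and Pdk4 at 1.26 on the log2 scale. The scores of this list overlapped, from 4.55 to 5.23 in T NDE and from 4.40 to 4.57 in T NC. Its T NDE mean of 4.80 was raised by the highest library. The labels give no time of day for the collection of the nodes. Monocyte genes had a median of -0.26 (adjusted p = 0.269 with an estimated correlation), with Chil3 at 10.9 ± 3.32 CPM in T NDE and 22.2 ± 1.69 CPM in T NC.

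In T NC against NT NC, Siglec1 averaged 163 ± 15.4 CPM and 244 ± 10.4 CPM (SD, n = 3), and the mannose receptor gene Mrc1 81.1 ± 10.6 CPM and 123 ± 8.61 CPM. The sinus macrophage list had a median of -0.24 (adjusted p = 0.736 with an estimated correlation), and 1 of 14 was lower when adjusted over the list alone. Its scores overlapped, from 6.04 to 6.37 in T NC and from 6.26 to 6.64 in NT NC (mean log2 CPM). In the fit of NT NDE and NT NC alone, edgeR calls that were higher in NT NDE included the NF-kB regulator Bcl3 (0.61), the sphingosine phosphate receptor S1pr3 (0.51) and Jak3 (0.41), and calls that were lower included the interferon-induced genes Usp18 (-0.84), Ifih1 (-0.61) and Mx1 (-0.93).

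Genes of gamma delta T cells appeared among the smallest p values of T NDE against T NC, and a hypothesis was that cells of the Tcrg-V6 type, which make interleukin 17, may be more abundant in the denervated tumour-bearing nodes. Apart from Sox13, Maf and Tcrg-V6, DESeq2 called Cd163l1 (log2 fold change 2.20), Trdc (1.58) and Tcrg-C2 (1.38) higher. A separate list of 18 transcripts of these cells, 16 of them tested, had a median log2 fold change of 0.35 in T NDE against T NC (camera p = 9.77e-07, p = 0.0264 with an estimated correlation), with 12 members higher and 5 past when adjusted over the list alone, among them Il23r (0.72) and Tcrg-C1 (1.71). The median was 0.13 without T NDE replicate 1, 0.22 without the 3 salivary libraries and 0.26 with the Bpifa2 covariate. Library scores were 4.90, 4.42 and 4.65 in T NDE and 4.41, 4.19 and 4.08 in T NC, and group means were 4.49 ± 0.10 in NT NDE and 4.36 ± 0.18 in NT NC (SD, n = 3). The interaction median was 0.24 (camera p = 0.0293, p = 0.267 with an estimated correlation). The median with all libraries lay above the 0.2 set beforehand for the hypothesis, but it missed that bound without T NDE replicate 1, so it depended on 1 library, and a change of transcripts per cell was not separated from a change in cell number.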
